A study of Homo sapiens with 14 samples.

How the data were processed

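The data came from 14 libraries of HCT116 cells, a human colorectal carcinoma line. Of these, 6 were ChIP-seq libraries made with the antibody 3E8 against RNA polymerase II phosphorylated at Ser5, and 8 were inputs, sheared chromatin sequenced without immunoprecipitation. Per the labels' protocols, cells were electroporated with or without the peptide, split into DMSO or Nutlin3a, fixed with formaldehyde after 3 h, and sheared by sonication. A KAPA kit was used for the libraries and an Illumina NextSeq for sequencing, per the labels' protocols. The values deposited by the authors were raw read counts in 1 window per gene at a transcription start site (TSS), with hg38 as the genome build per the submitters' processing notes. The aligner, the counting tool and the read filters were not given in the sources used here. Per the file headers the authors also deposited a scaled signal for each ChIP library, and its values were the counts times 1 constant per library. The derivation of that constant was not given in the sources used here, and the signal entered only as an alternative scaling.

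The table held 28159 windows of 1000 bp, 1 per gene. The most common placement ran from 300 bp upstream to 700 bp downstream of the annotated gene start. It was found for 10167 of the 23681 genes with an annotated gene boundary inside their window. Gene symbols were as in the table, and 27791 of them (98.7%) matched a RefSeq gene of the GRCh38 assembly, which gave biotypes and neighbouring genes. Windows are 1-based. In total 571 genes shared an exact window with another gene, and 6188 genes (22.0%) had a window that overlapped another gene's. Reads in an overlap count for both genes, so such genes are uncertain. The counts carry no stated strand, so a gene and an antisense partner cannot be told apart. No sample column was left unused.

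Groups were taken from the sample titles and treatment labels. DMSO and Nutlin3a without peptide had 2 ChIP libraries each, and each peptide group had 1. The comparisons were Nutlin3a against DMSO without peptide, the same with peptide, the difference between these responses, and the peptide against no peptide under each treatment. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, in the setting legacy=TRUE that the installed version uses by default). Library sizes were scaled by TMM, with factors from 0.951 to 1.02. Windows were filtered with filterByExpr (minimum count 10), which left 25901. A single fit of 4 group means to the 6 ChIP libraries had 2 residual degrees of freedom, 14.7 prior degrees of freedom and a biological coefficient of variation of 26.0%. The spread in that fit comes from the DMSO and Nutlin3a pairs, and the lone library of each peptide group was assumed to vary like them. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Errors of log2 fold changes are standard errors from the fit, and intervals are 95% intervals. Log2 ratios within a replicate number used TMM-scaled CPM (counts scaled to a common library size) with a prior count of 2. Nutlin3a against DMSO with peptide compares 1 library with 1 library, so it was given as values and percentiles and was not tested on its own.

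In all, 22 gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists. Of these, 1 held 114 p53 targets, and 5 held its members for feedback, arrest, cell death, DNA repair and metabolism. The others covered cell cycle genes bound by the DREAM repressor complex, immediate early genes, heat shock, ATF4 and endoplasmic reticulum stress, NF-kB, interferon, cholesterol and lipid synthesis, hypoxia, NRF2 targets, Mediator subunits, ribosomal proteins and replication histones, plus markers of colon epithelium, blood cells, mesenchyme and silent tissues. Each list's median was also placed among the medians of 10000 random lists of the same size matched on mean abundance. Lists, comparisons, tests and most alternatives were fixed before the data were examined. So was the rule for naming genes. It took those past the threshold with the largest fold changes or, where none passed, the 5 with the smallest p in each direction. To these it added 25 genes named whatever their values and, from each list that passed, up to 4 members with the smallest p. Some genes that this rule names are not reported here. A further set was the 50 genes with the highest Nutlin3a to DMSO ratio in replicate 1, read in replicate 2, which removes the selection from the value read.

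The test was tested on simulated data drawn from the real means and library sizes, with genes above the median abundance changed in both directions. In the simulated Nutlin3a against DMSO comparison over 25901 windows, 4.48% of 67 genes changed 1.5-fold, 31.3% of 67 changed 2-fold and 97.0% of 66 changed 4-fold passed the threshold. For the simulated difference between the responses with and without peptide, these shares were 0%, 1.49% and 24.2%. The simulated counts held no difference between replicate numbers, unlike the data. Among unchanged simulated genes 4.86% had an unadjusted p under 0.05 in Nutlin3a against DMSO. In the data only 601 of all 25901 windows did, where chance alone would give 1295, so the shares may be too high for the data. Alternatives covered the scaling, the count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, windows with ChIP CPM at least 2 times input CPM, the 4 libraries without peptide fitted alone, and each DMSO and Nutlin3a library left out in turn. Alternatives chosen after seeing the data were the setting legacy=FALSE, the authors' constants as scaling, 1 gene per distinct window, and 3 further readings of the set of 50. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.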

Results

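RNA polymerase II phosphorylated at Ser5 of its C-terminal domain, a form enriched at promoters and early in transcription, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with the antibody 3E8. The cells were HCT116, a human colorectal carcinoma line. Cells were electroporated with or without a bivalent stapled peptide at 10 µM, and the peptide samples received a further 200 nM in the medium. They were then kept for 3 h in 0.1% DMSO, the solvent, or in 10 µM Nutlin3a, which blocks the binding of MDM2 to p53 and so stabilises p53. Per the series, the peptide is meant to block the contact between p53 and Mediator, the complex that links transcription factors to the polymerase. There were 2 ChIP libraries for DMSO and 2 for Nutlin3a without peptide, 1 for DMSO with peptide and 1 for Nutlin3a with peptide, both of these being replicate 2. Each of the 4 conditions had 2 inputs. Total counts in the windows were 2186520 (replicate 1) and 1952467 (replicate 2) for DMSO and 1290223 and 1634929 for Nutlin3a. The peptide libraries held 1775860 counts for DMSO and 2240951 for Nutlin3a. Inputs held 161719 to 359276 counts. Whether the replicates are separate cultures or technical repeats was not given in the sources used here, and in the second case the p-values measure only the spread between these samples.

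The replicate 1 libraries stood apart from the replicate 2 libraries. The first principal component held 53.3% of the variance and placed DMSO replicate 1 at −33.0 and Nutlin3a replicate 1 at −112, against 16.2 to 46.5 for the replicate 2 libraries. Spearman correlations across genes were 0.964 to 0.974 among the replicate 2 libraries, 0.935 between the DMSO libraries and 0.891 between the Nutlin3a libraries, with genes not being independent replicates. Nutlin3a replicate 1 also had the highest background. At 29 windows of silent tissue genes and of the blood cell and mesenchymal markers, its median was 8.53 CPM (counts scaled to a common library size), against 4.12 to 6.73 CPM in the other ChIP libraries. The share of its counts in mitochondrial windows was 0.122%, against 0.00948% to 0.0295%. The tenth of windows with the highest ChIP signal held 39.1% of its counts, against 40.8% to 42.9% in the other ChIP libraries and 26.4% to 28.9% in the inputs. Of the tested windows, 9.62% had a mean ChIP CPM at least 2 times the mean input CPM. Each library was scaled to its own counts in the windows, so this ratio ranks windows and does not measure absolute enrichment over input.

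Nutlin3a against DMSO without peptide asked which promoters gained or lost Ser5-phosphorylated polymerase after p53 was stabilised. Signal rose at TP53INP1, a p53 target in autophagy and cell death, by a log2 fold change of 1.57 ± 0.23 (SE, n = 2 per group), or 2.98-fold. It also rose at the microRNA gene MIR3189, by 1.73 ± 0.24, whose window overlaps that of GDF15. GDF15, a stress cytokine and p53 target, was at 1.33 ± 0.22 and passed when adjusted over the list alone. Of 112 tested members of the p53 target list, 17 were higher and 0 lower when adjusted over the list alone, with TP53INP1 the 1 member higher over all genes. They included SESN1, a sestrin that restrains mTORC1 (1.73 ± 0.30), BBC3, which encodes the death factor PUMA (1.56 ± 0.26), and FAS, a death receptor (1.47 ± 0.25, window shared in part with ACTA2). CDKN1A, which encodes the cell cycle inhibitor p21, was 2.62-fold higher (1.39 ± 0.25, window shared in part with the noncoding gene DINOL). Its level was 116 ± 13.2 CPM (SD, n = 2) with DMSO and 303 ± 76.1 CPM with Nutlin3a, against a mean of 53.8 CPM in the inputs. MDM2, the ligase that degrades p53, was 1.78-fold higher (0.84 ± 0.22), with 102 ± 2.26 CPM and 181 ± 16.1 CPM. The others were CYFIP2 (1.26), PHLDA3 (1.16), TNFRSF10C (1.11), RPS27L (1.04), BTG2 (0.89), SYTL1 (0.89), CCNG1 (0.88), DDB2 (0.87), SESN2 (0.77) and REV3L (0.72). The count of 17 higher members depended on the processing. It was 6 with the authors' constants, 20 with total counts and 24 with a mean count of at least 50. In windows with ChIP at least 2 times input, where fewer windows were tested, it was 7. 

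**Figure D1:**
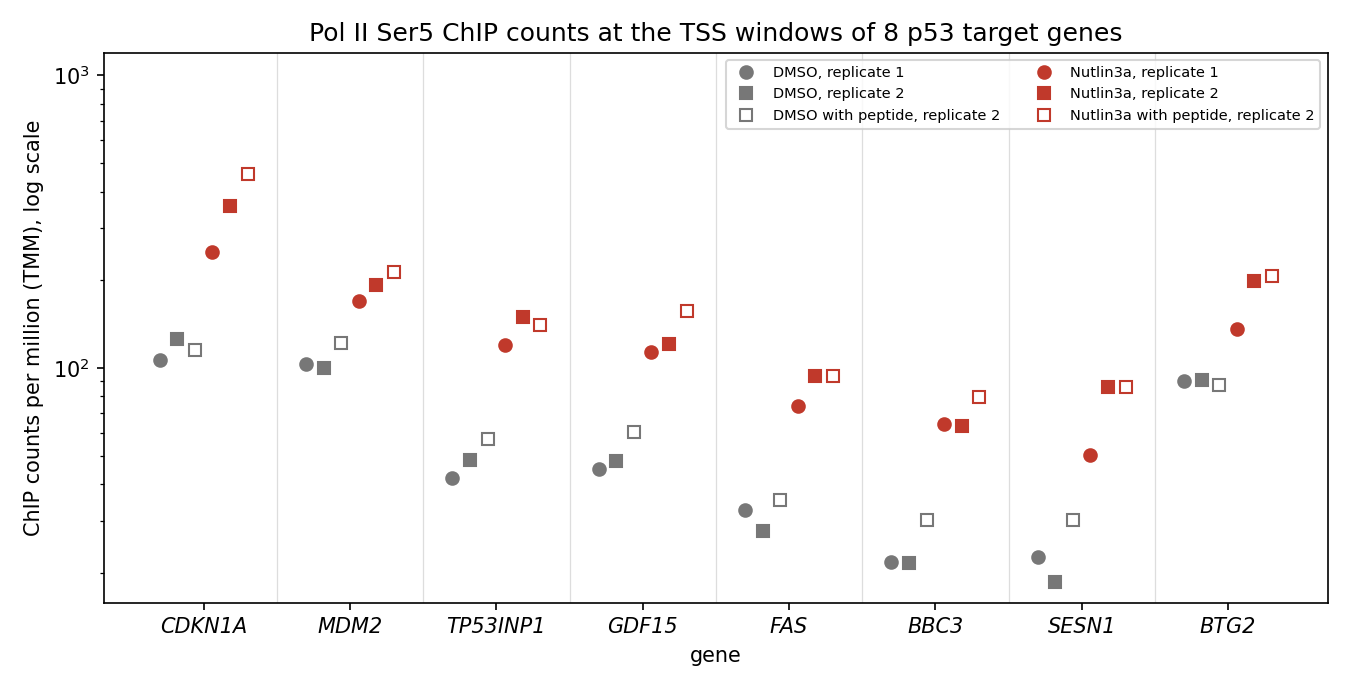
Scaled counts (CPM, log axis) at 8 p53 target windows in each of the 6 ChIP libraries, with 1 point per library. CDKN1A lay at 303 CPM on average in the Nutlin3a libraries without peptide and at 461 CPM in the Nutlin3a library with peptide.

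By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 25901 windows, 2 genes were higher (adjusted p = 0.0356 for MIR3189 and 0.0379 for TP53INP1) and 0 were lower. The fit did not pair libraries by replicate number, although the protocol split electroporated cells between DMSO and Nutlin3a. With that number as a block more genes were higher, as given below among the alternatives. At an unadjusted p under 0.05 there were 330 higher and 271 lower genes, where chance alone would give 1295, DESeq2 called 8 higher and 0 lower, and limma-voom 4 and 0. Neither direction had a call with a mean count of at least 50, in windows with ChIP at least 2 times input, with the 4 libraries without peptide alone, with legacy=FALSE or with the authors' constants. CDKN1A had an adjusted p of 0.109 over all genes and 0.000552 over the list alone by the same edgeR test, and MDM2 had 0.98 and 0.0144. Windows on chromosomes 8 and 19 held TP53INP1 (94949079 to 94950078) and GDF15 (18385858 to 18386857) in hg38, and the MIR3189 window ran from 18386262 to 18387261. CDKN1A lay on chromosome 6 (36678414 to 36679413) and MDM2 on chromosome 12 (68807872 to 68808871). The number of genes called higher was 88 without DMSO replicate 1, 0 without DMSO replicate 2, 17 without Nutlin3a replicate 1 and 37 without Nutlin3a replicate 2. Lower genes numbered 15 without Nutlin3a replicate 1 and 2 without Nutlin3a replicate 2.

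Across the whole p53 list the median log2 fold change was 0.20 and 79 of 112 members were positive, above 100% of random lists matched on abundance. The median was 0.16 in replicate 1 and 0.29 in replicate 2. The camera test gave an adjusted p of 8.27e-09 for the list, with adjusted p = 0.442 with an estimated correlation and 0.391 with fry. The feedback members had a median of 0.50 (4 of 6 positive, camera adjusted p = 0.00022, and adjusted p = 0.442 with an estimated correlation), with MDM2, CCNG1 and TP53INP1 higher and COP1, a ligase that degrades p53, lower (−0.56 ± 0.23), when adjusted over the list alone, here the 6 feedback members. COP1 was at −0.31 without Nutlin3a replicate 1, −0.90 without Nutlin3a replicate 2 and −0.16 with the authors' constants, and did not pass over the 112 members. Arrest members had a median of 0.30 (9 of 12, adjusted p = 1.64e-05, and adjusted p = 0.442 with an estimated correlation) and cell death members 0.22 (16 of 20, adjusted p = 1.14e-06, and adjusted p = 0.442 with an estimated correlation). DNA repair members, such as DDB2, which binds ultraviolet lesions, had a median of 0.33 (6 of 7, adjusted p = 0.0013, and adjusted p = 0.443 with an estimated correlation). Metabolism members, such as SESN1, had a median of 0.12 (11 of 16, adjusted p = 0.00661, and adjusted p = 0.711 with an estimated correlation). Fry's test for change in either direction passed for the feedback members, with an adjusted p of 0.0401. Not every known target passed over the list alone: BAX was at 0.31, ZMAT3 at −0.02, TIGAR at −0.02, RRM2B at 0.33, PPM1D at 0.17, PLK3 at 0.26, FDXR at 0.46, XPC at 0.59 and TP53I3 at 0.66. The rule for naming genes also gave E2F7 (0.44), FANCC (−0.43) and ACER2 (0.58). Calls ended without DMSO replicate 2 for feedback (median 0.40), DNA repair (0.20) and metabolism (0.06), and for metabolism also without Nutlin3a replicate 2 (−0.09) and in windows with ChIP at least 2 times input (0.25). Without DMSO replicate 1 the medians of cell death (0.34), DNA repair (0.55) and metabolism (0.18) moved by over 1.5 times, as did cell death without DMSO replicate 2 (0.13) and metabolism without Nutlin3a replicate 1 (0.20).

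For ribosomal protein, cell cycle and immediate early genes in Nutlin3a against DMSO without peptide, the sign of the median depended on the scaling. It was negative with TMM, DESeq2's size factors and total counts, and positive only with the authors' constants. The constant was 1.82 for Nutlin3a replicate 1, the library with the highest background, against 0.595 to 0.748 for the other ChIP libraries. Scaled total counts for DMSO and Nutlin3a were 1446450 and 2348590 in replicate 1, and 1161910 and 1222940 in replicate 2. The authors' constants moved the median of all genes from 0.04 to 0.53. The medians of these lists stayed below that of all genes there. The ribosomal protein and cell cycle calls held with the constants (camera adjusted p = 0.00127 for each). Ribosomal protein genes had a median of −0.24 (0.29 by the authors' constants), with 4 of 73 positive (camera adjusted p = 4.05e-11, and adjusted p = 0.442 with an estimated correlation). Examples were RPS14 (−0.46) and RPL26 (−0.45), and RPL12 (−0.44) and RPL7A (−0.42) share windows in part with LRSAM1 and MED22. The ribosomal protein median lay inside the range of matched random lists (−0.25 to −0.16), as did that of the immediate early genes (−0.26 to −0.09), and that of the cell cycle genes lay below its range (−0.22 to −0.06). Cell cycle genes bound by the DREAM complex had a median of −0.31 (0.24 by the authors' constants), with 4 of 34 positive (adjusted p = 1.77e-07, and adjusted p = 0.608 with an estimated correlation). The replication helicase genes MCM5 (−0.61), MCM4 (−0.55, shared in part with PRKDC) and MCM7 (−0.44, shared in part with AP4M1) and the replication licensing gene CDC6 (−0.40) were examples. Immediate early genes, the first to respond to growth signals, had a median of −0.16 (0.32 by the authors' constants) with 8 of 25 positive (adjusted p = 0.0287, and adjusted p = 0.443 with an estimated correlation). They included KLF6 (−0.41), PHLDA1 (−0.33), FOS (−0.27) and EGR1 (−0.27), with ATF3 at 0.46 ± 0.26 (0.96 without DMSO replicate 1 and 0.11 without DMSO replicate 2). None of their members passed edgeR's test adjusted over the list alone. Mesenchymal markers such as COL1A2 (0.91), TWIST1 (0.79), PDGFRB (0.87) and DCN (2.79) had few counts and a median of 0.87 (6 of 7 positive, adjusted p = 0.0474, and adjusted p = 0.663 with an estimated correlation). That median was 1.25 in replicate 1, whose Nutlin3a library had the highest background, and 0.09 in replicate 2. MYC, a growth regulator, was at −0.42 ± 0.24 and the heat shock gene HSPA1A at −0.07.

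Among windows with ChIP at least 2 times input the cell cycle call ended (0.00) and the ribosomal protein median was −0.05, and with a mean count of at least 50 the medians were −0.17 and −0.09. The immediate early call ended with total counts, with a mean count of at least 50, in windows with ChIP at least 2 times input and with the authors' constants (medians −0.09, −0.05, −0.10 and 0.32), and the mesenchymal call with total counts, no filter, DESeq2, limma-voom and the authors' constants (0.76 to 1.40). The cell cycle call ended without DMSO replicate 1 (−0.14) and Nutlin3a replicate 2 (−0.14), and the immediate early call without the same libraries (−0.10 and −0.15). The mesenchymal call ended without DMSO replicate 1 (0.43), Nutlin3a replicate 1 (0.71) or Nutlin3a replicate 2 (0.88). The remaining 12 lists passed no camera test. Their medians were −0.08 for heat shock, 0.06 for ATF4 and endoplasmic reticulum stress, −0.04 for NF-kB, 0.60 for interferon, −0.05 for cholesterol and lipid synthesis, −0.04 for hypoxia and 0.03 for NRF2 targets. Mediator subunits were at −0.12, replication histones at −0.04, colon epithelial markers at −0.06 and blood cell markers at 0.29. Silent tissue genes were at 0.57, with 0.95 in replicate 1 and 0.00 in replicate 2.

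**Figure D2:**
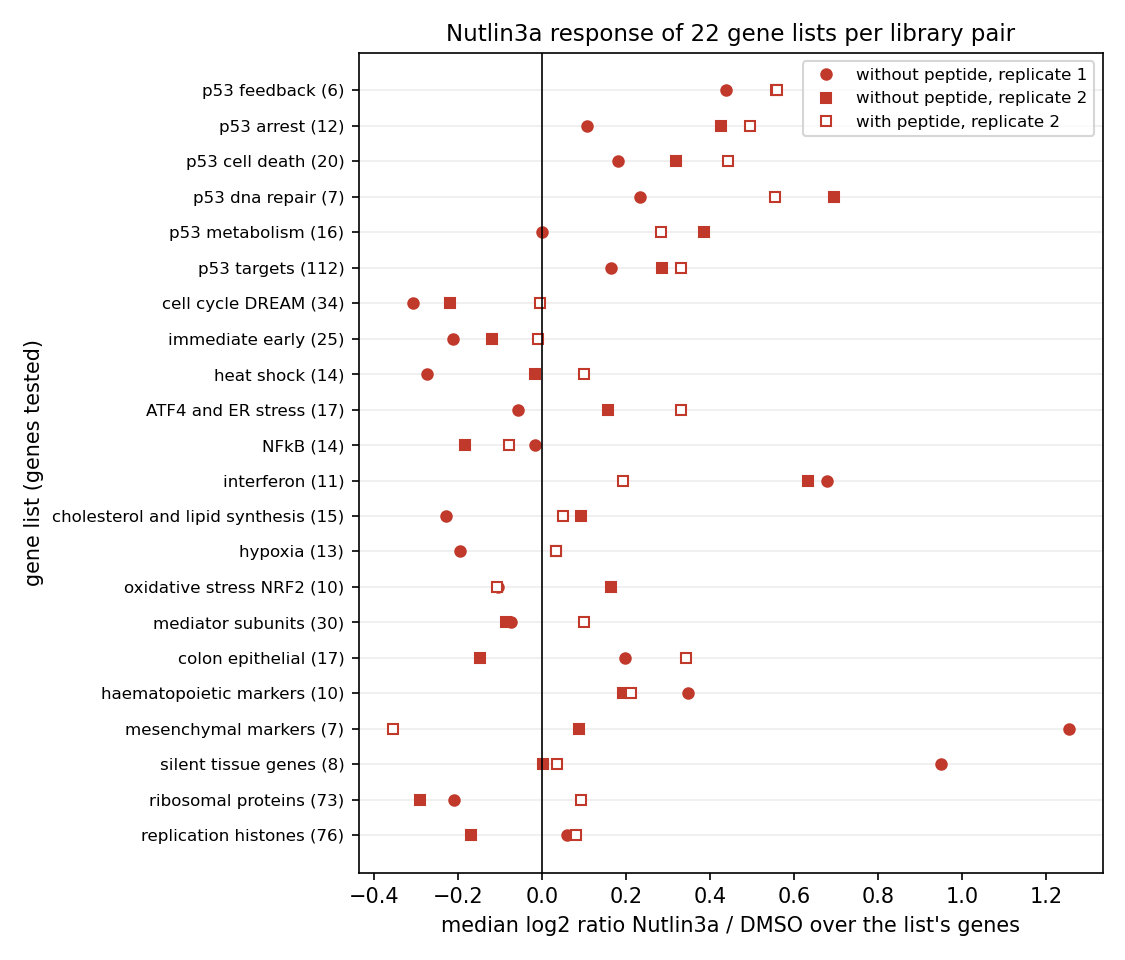
Median log2 ratio of Nutlin3a to DMSO for each of 22 gene lists in replicate 1, in replicate 2 and in replicate 2 with peptide, with 1 point per pair of libraries. The p53 list lay at 0.16, 0.29 and 0.33 in that order.

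With peptide, Nutlin3a against DMSO asked whether the same promoters respond in its presence, and with 1 library per group it was given as values and not tested on its own. The 17 p53 targets that were higher without peptide had a median log2 ratio of 1.11 with it, against 0.98 in replicate 1 and 1.12 in replicate 2 without it, values that their selection raises. CDKN1A was 4.01-fold higher (115 CPM with DMSO, 461 CPM with Nutlin3a), MDM2 1.75-fold (122 and 213 CPM) and TP53INP1 2.45-fold (57.1 and 140 CPM). SESN1 was at a log2 ratio of 1.51, FAS at 1.41, BBC3 at 1.40, GDF15 at 1.38 and BTG2 at 1.24. The whole p53 list had a median of 0.33 with 87 of 112 positive, above 100% of matched random lists. Feedback (0.56), arrest (0.50), cell death (0.45), DNA repair (0.56) and metabolism members (0.29) all had positive medians, as did the ATF4 and endoplasmic reticulum stress genes (0.34). Cell cycle genes were at −0.00, immediate early genes at −0.01 and ribosomal protein genes at 0.09. BAX was at 0.82 and ATF3 at 1.02. Across the 112 p53 genes the fitted changes without and with peptide, which share no library, had a Pearson correlation of 0.262 and a Spearman correlation of 0.596. Across 12849 other genes above the median abundance these were 0.0735 and 0.0732, and genes are not independent replicates. For log2 ratios of the p53 genes in replicate 2, without against with peptide, the Pearson and Spearman correlations were 0.572 and 0.593. Between replicates 1 and 2 without peptide they were 0.604 and 0.585.

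**Figure D3:**
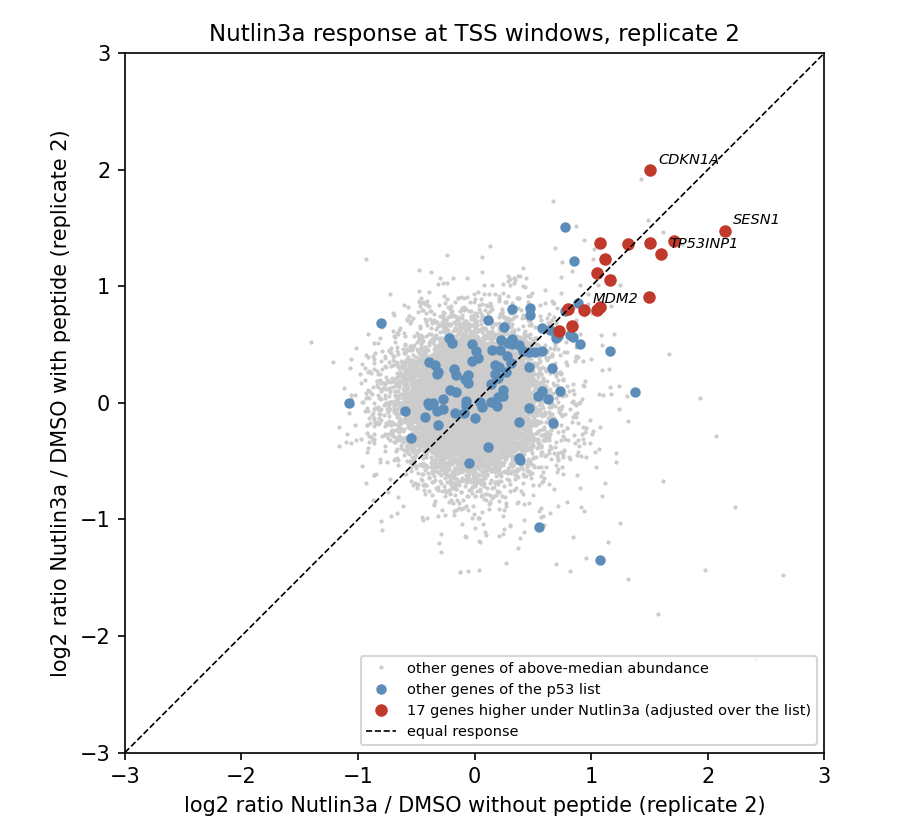
Log2 ratio of Nutlin3a to DMSO in replicate 2 without peptide (x axis) and with peptide (y axis), with grey points for genes above the median abundance, blue for the p53 list and red for the 17 p53 targets that were higher without peptide. The dashed line marks equal ratios, and 6 of the 17 lay above it.

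The difference between the Nutlin3a responses with and without peptide asked whether the peptide changes the response. Over the 17 responding p53 targets the median difference in log2 was −0.06, with 7 positive, and none was past the threshold. Their selection for a high response without peptide lowers this difference, and over the 19 p53 targets named whatever their values the median was 0.08 with 11 positive. The difference was 0.62 for CDKN1A, or 1.53-fold (95% interval 0.831 to 2.83), and −0.03 for MDM2 (log2 interval −0.82 to 0.76). It was −0.28 for TP53INP1 (−1.10 to 0.54), −0.22 for SESN1 (−1.28 to 0.83) and 0.05 for GDF15 (−0.74 to 0.84). As a fold, the MDM2 response with peptide was 0.979 of that without it, with an interval of 0.567 to 1.69, which ran from a loss of nearly all of its 1.78-fold response to a larger response. The median interval of the 17 reached 0.87 to either side. Ribosomal protein genes had a median difference of 0.35 with 67 of 73 positive, from −0.24 without peptide to 0.09 with it (camera adjusted p = 8.15e-10, and adjusted p = 0.663 with an estimated correlation). Examples were RPL36A (1.15), RPL24 (0.93), RPS13 (0.80) and RPS14 (0.69). Cell cycle genes had a median of 0.29 (28 of 34, adjusted p = 0.00851, and adjusted p = 0.667 with an estimated correlation), with MCM5 (0.79), AURKA (0.62), CDC20 (0.56) and CDC25C (0.53). Immediate early genes had 0.29 (17 of 25, adjusted p = 0.0487, and adjusted p = 0.663 with an estimated correlation), with PHLDA1 (0.66) and IER3 (0.52). The p53 list had 0.18 (78 of 112, adjusted p = 0.0185, and adjusted p = 0.663 with an estimated correlation), with KRT8 (0.68), BCL2L1 (0.66), BLCAP (0.65) and ALOX5 (−1.80). That median lay inside the range of matched random lists (0.08 to 0.23), as did the immediate early median (0.07 to 0.33). The ribosomal protein median lay above its range (0.16 to 0.30) and the cell cycle median just above its own (0.04 to 0.28). Random genes of like abundance thus also had positive differences.

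By edgeR's quasi-likelihood test 0 genes passed for this difference, with 107 higher and 166 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0. Those with the smallest p were BTK (1.35 ± 0.43, shared in part with RPL36A), RAB22A (1.26), PPP4R1L (1.22), BICD1 (1.19) and MIR4658 (1.67), and, in the other direction, GPRC5B (−2.81), DENND11 (−2.01), CTAGE15 (−1.28) and AMZ1 (−2.56). ZNF705G, with 0 counts in the Nutlin3a library with peptide, was the other lower gene. Other values were 0.51 for BAX, 0.55 for ATF3, 0.40 for FOS, 0.35 for EGR1, 0.38 for HSPA1A and 0.29 for MYC. With a mean count of at least 50 the cell cycle (0.11), immediate early (0.17) and p53 calls (0.05) ended and the ribosomal protein median was 0.19, and that median was 0.15 in windows with ChIP at least 2 times input and 0.23 with the authors' constants. The other 3 calls also ended with the authors' constants (0.13, 0.17 and 0.10) and in windows with ChIP at least 2 times input (−0.05, 0.17 and 0.07), and 2 of them, immediate early and p53, with total counts (0.21 and 0.10). The immediate early call ended with DESeq2's size factors as well (0.27). The p53 call ended also without DMSO replicate 1 (0.12) and Nutlin3a replicate 1 (0.10). The cell cycle call ended without DMSO replicate 1 (0.05) and Nutlin3a replicate 2 (0.11), and the immediate early call without the same libraries (0.10 and 0.19). Without DMSO replicate 1, 34 genes passed, and without Nutlin3a replicate 2, 5 did.

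Peptide against no peptide under Nutlin3a asked how the peptide alters polymerase once p53 is stabilised. By the authors' constants the median of all genes was −0.33 and those of all 7 passing lists were negative (−0.22 to −0.00), so every direction here is relative to the scaling. The constant was 1.82 for Nutlin3a replicate 1, 0.748 for Nutlin3a replicate 2 and 0.638 for Nutlin3a with peptide. Scaled total counts were 2348590, 1222940 and 1429150 in that order, so the library with peptide lay below replicate 1 but above replicate 2. Ribosomal protein genes had a median of 0.24 (−0.11 by the constants, 63 of 73 positive, camera adjusted p = 8.66e-09, and adjusted p = 0.583 with an estimated correlation), with RPS14 (0.78) and RPL10 (0.52). The p53 list was at 0.12 (−0.18 by the constants, 77 of 112, adjusted p = 0.00103, and adjusted p = 0.651 with an estimated correlation), arrest members at 0.28 (−0.00 by the constants, 11 of 12, adjusted p = 0.00103, and adjusted p = 0.583 with an estimated correlation) and cell death members at 0.18 (−0.09 by the constants, 16 of 20, adjusted p = 0.00284, and adjusted p = 0.583 with an estimated correlation). Values were 0.60 ± 0.28 for CDKN1A, 0.60 ± 0.25 for the death receptor gene TNFRSF10B (shared in part with LOC286059), 0.54 for BTG1, 0.50 for PLK2, 0.42 for GDF15 and 0.55 for BCL2L1. Cell cycle genes were at 0.18 (−0.22 by the constants, 22 of 34, adjusted p = 0.005, and adjusted p = 0.862 with an estimated correlation), with the cyclin gene CCNA2 (0.64) and the mitotic kinase gene PLK1 (0.46). ATF4 and endoplasmic reticulum stress genes were at 0.28 (−0.05 by the constants, 15 of 17, adjusted p = 0.00833, and adjusted p = 0.651 with an estimated correlation), with the chaperone gene HSPA5 (0.71 ± 0.25), DDIT4 (0.47), ATF4 (0.40) and SLC7A11 (−3.64). Immediate early genes were at 0.16 (−0.13 by the constants, 16 of 25, adjusted p = 0.00724, and adjusted p = 0.583 with an estimated correlation), with CCN1 (0.84), ATF3 (0.74) and DUSP6 (−0.67). The medians of the p53 list (0.03 to 0.14), cell death members (−0.03 to 0.21) and immediate early genes (0.02 to 0.23) lay inside the ranges of their matched random lists.

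For this comparison 0 genes passed edgeR's quasi-likelihood test, with 146 higher and 486 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0. The smallest p belonged to SNORD88B (0.87), SELENOH (0.80), BANK1 (1.19), GPRC5A (0.78) and ABCB8 (0.97), and to ROCK1P1 (−3.96), ZBTB20 (−4.85), FAM230B (−4.93), LINC00999 (−2.95) and OR4F16 (−5.25), of which ROCK1P1, FAM230B and OR4F16 have near copies elsewhere in the genome. With a mean count of at least 50 all of these list calls ended except those for arrest members and ribosomal protein genes (0.14), and the stress (0.02), cell cycle (0.08) and immediate early calls (0.08) ended in windows with ChIP at least 2 times input. With the authors' constants all 7 ended except that for ribosomal protein genes, whose median was negative there but above that of all genes. Lower genes numbered 77 without DMSO replicate 1, 96 without DMSO replicate 2, 2 without Nutlin3a replicate 1 and 131 without Nutlin3a replicate 2, which also gave 8 higher genes. Without Nutlin3a replicate 1 the p53 (0.05) and cell death calls (0.09) ended and the cell cycle median was 0.33. Without Nutlin3a replicate 2 the cell cycle (−0.02), immediate early (0.23) and stress calls (0.27) ended, and the p53 list was at 0.21 and cell death at 0.32.

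Peptide against no peptide under DMSO asked whether the peptide acts without Nutlin3a. CDKN1A was at −0.01 and MDM2 at 0.26, and the p53 list had a median of −0.04 with 51 of 112 positive (camera adjusted p = 0.951). No list passed: medians were −0.41 for interferon, −0.12 for Mediator subunits, 0.89 for mesenchymal markers, −0.09 for ribosomal protein genes and −0.20 for replication histones, each with a camera adjusted p of 0.0896, the smallest. By edgeR's quasi-likelihood test 0 genes passed, with 178 higher and 215 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0. Genes with the smallest p included MOV10L1 (2.02), MYO5C (1.02 ± 0.31), GPRC5B (1.83), LOC100128108 (1.67) and RGS6 (1.75) and, in the other direction, STK38 (−1.13), CDH1, which encodes E-cadherin (−1.07 ± 0.33), SNORD81 (−2.38) and LINC02762 (−3.20). Without DMSO replicate 2, 53 genes were lower, and without Nutlin3a replicate 1, 24 were. The authors' constants moved the median of all genes to −0.25 here.

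The 50 genes with the highest Nutlin3a to DMSO ratio in replicate 1 had a median log2 ratio of 1.42 there, by their selection. In replicate 2, which took no part in the choice, the median was 0.36, above 100% of matched random lists (range −0.11 to 0.12), and 3 of the 50 were in the p53 list. The 50 included copies of the CT45A and GAGE families, with near-identical windows, and mitochondrial and small nucleolar RNA windows such as RNR1, RNR2 and SNORD118. In total 32 of the 50 were copies, pseudogenes or windows of these kinds. With peptide it was −0.01, above 39.8% of random lists, with 24 of 50 higher. The median difference with and without peptide within replicate 2 was −0.13, above 4.98% of random lists (range −0.15 to 0.16). A set of 50 chosen without such windows, an alternative chosen after seeing the data, had medians of 0.22 without and 0.28 with peptide, and the difference was 0.07. Genes chosen in replicate 2 instead, of which 12 were in the p53 list, had a median of 0.68 in replicate 1. As background, the same fit to the inputs gave Nutlin3a to DMSO values without peptide of −0.40 ± 0.68 for CDKN1A, −0.52 ± 0.66 for MDM2 and −0.65 ± 0.62 for TP53INP1 (n = 2 per group). BBC3 was at 1.46 ± 0.98, close to its ChIP value, MIR3189 at 0.66 ± 0.66 and FAS at 0.58 ± 0.86, none past the threshold. The p53 list had a median of −0.04 in the inputs and the 17 responding targets 0.12, above 68.3% of matched random lists. By edgeR's quasi-likelihood test the inputs gave 0 genes for Nutlin3a against DMSO without peptide, with 870 at an unadjusted p under 0.05. In the other comparisons of inputs, 7 genes were higher for Nutlin3a with peptide, 5 for the difference and 3 for the peptide under Nutlin3a, and 5 were lower for the peptide under DMSO. The inputs' p53 list median for Nutlin3a with peptide was 0.09, above 98.2% of matched random lists.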

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

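The value of the p53 list in replicate 2 alone was planned, but the tests on replicate 2 alone were chosen only after the result was seen. Tests on ChIP enrichment were written after the trend of the response with enrichment had been seen but before their own result.

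Ribosomal protein genes had a median Nutlin3a response of −0.24 without peptide and 0.09 with it, and a median log2 difference of 0.35 by a test of that difference (camera adjusted p = 8.15e-10, and adjusted p = 0.663 with an estimated correlation). A lower ChIP enrichment in the Nutlin3a libraries without peptide was argued against as the whole cause. The median exceeded 99.9% of random lists matched on abundance and on the ChIP to input ratio. Those lists had a range of 0.17 to 0.31, so a positive difference was shared by other genes of like abundance and ratio. In windows with ChIP at least 2 times input the difference was smaller (0.15, camera adjusted p = 0.0024). The replicate 1 libraries, which have no ChIP counterpart with peptide, were argued against as well, because replicate 2 alone gave 0.38, outside the range of matched random lists (0.04 to 0.21). The same genes had a median of 0.07 in the inputs. The peptide stays open as untested, since each peptide group had 1 ChIP library, and GC content was not tested because no genome sequence was used here.

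The difference was also positive for the cell cycle (0.29, from −0.31 without peptide to −0.00 with it), immediate early (0.29, from −0.16 to −0.01) and p53 lists (0.18, from 0.20 to 0.33) by the same test, each at an adjusted p of 0.663 or above with an estimated correlation. Among random lists matched on abundance and ChIP to input ratio their medians stood at percentiles 96.9, 85.9 and 65.9, inside the central ranges, so a lower enrichment of the Nutlin3a libraries without peptide stays open for all 3. In replicate 2 alone their medians were 0.21, 0.14 and 0.053, each inside its range for matched random lists, so the replicate 1 libraries stay open too. The inputs gave medians of −0.30, −0.19 and 0.05. The peptide stays open as untested.

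The inputs, whose groups were compared only as background, held a median of 27.9% of their counts in the tenth of windows with the highest ChIP signal, where an even spread over windows would give 10.0%.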

How the results depend on the processing

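Alternatives chosen only after the data were seen were the setting legacy=FALSE, the authors' constants, 1 gene per distinct window, the reading with peptide of genes chosen in replicate 2, and the sets of genes chosen in replicate 1 among windows with ChIP at least 2 times input or without copies, pseudogenes, mitochondrial and small nucleolar RNA windows. The cause was not tested for any change given here.

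Genes higher with Nutlin3a without peptide, 2 as reported, numbered 8 with total counts, 8 with DESeq2, 4 with limma-voom, and 0 with a mean count of at least 50, in windows with ChIP at least 2 times input, with legacy=FALSE, with the authors' constants and with the 4 libraries without peptide alone. Leaving out 1 library gave 0 to 88 higher and 0 to 15 lower. The counts of 0 became 0 to 34 for the difference between responses. Under Nutlin3a, peptide against no peptide gave 0 to 8 higher and 2 to 131 lower, and 55 lower with the authors' constants. Under DMSO it gave 0 to 53 lower. The protocol split electroporated cells between DMSO and Nutlin3a, but the labels do not say that a replicate number marks a shared split. With the replicate number as a block, 39 genes were higher with Nutlin3a, 13 of them in the p53 list. CDKN1A had an adjusted p of 1.09e-09 and MDM2 one of 0.0145 by edgeR, against 0.109 and 0.98 without the block. The prior degrees of freedom were infinite with the block, against 14.7 without it. Each window thus took its spread from the trend over all windows and not from its own counts, so these p-values may be too small. The 39 also included DINOL, ACTA2, GRIN2C, MIR34AHG, HELZ, APOBEC3H, the mitochondrial RNR1, RNR2 and MIR12136, ROCK1P1 and SNORD windows. For the difference 5 passed (RNR1, RNR2, MIR12136, ROCK1P1 and LOC101928626), 1 was lower with peptide under Nutlin3a (ROCK1P1) and 4 were higher with peptide under DMSO (the same 5 without ROCK1P1). In that paired fit, with 1 residual degree of freedom, the mesenchymal call ended (median 0.80). The difference between replicates 1 and 2 under DMSO correlated with that under Nutlin3a at 0.454 across the tested genes, which are not independent.

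The p53 median without peptide (0.20) was 0.29 in replicate 2 alone, 0.31 with a mean count of at least 50, 0.33 with ChIP at least 2 times input and 0.70 with the authors' constants, which put all genes at 0.53. With peptide (0.33) it was 0.43 in windows with ChIP at least 2 times input and 0.74 with the authors' constants. The difference between responses (0.18) was 0.10 with total counts, 0.047 with a mean count of at least 50, 0.074 with ChIP at least 2 times input and 0.10 with the authors' constants, with the call ended in all 4. It was 0.053 in replicate 2 alone, where no camera test was made, and 0.10 to 0.24 with 1 library left out. For peptide against no peptide under Nutlin3a (0.12) it was 0.048 with a mean count of at least 50 and 0.050 to 0.21 with 1 library left out. Its sign reversed to −0.18 with the authors' constants, which put all genes at −0.33. Of 21 camera calls, 0 passed with an estimated correlation and 0 by fry's directional test. Over the 17 responding p53 targets, the median difference between responses (−0.06) ran from −0.21 with a mean count of at least 50 to 0.11 without Nutlin3a replicate 2.

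For the 50 genes chosen in replicate 1, the replicate 2 median (0.36) was 0.23 without a filter, 0.30 with a mean count of at least 50, 0.14 for the top 100, 0.68 for genes chosen in replicate 2 and 0.22 without copies and the other windows named above. With peptide (−0.01) it was 0.080 with a mean count of at least 50, 0.21 for genes chosen in replicate 2, 0.21 with ChIP at least 2 times input and 0.28 without those windows. The difference (−0.13) was −0.021 with a mean count of at least 50, 0.076 for the top 25, 0.037 for the top 100, −0.045 with ChIP at least 2 times input and 0.075 without those windows.

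Of 955 values of single genes, 911 stayed on their side of the threshold, 52 of them with the other sign and past it in neither case. Another 36 passed anew, 8 no longer passed and 0 reversed past the threshold. Among these genes only MIR3189 and TP53INP1 passed as reported, so nearly all the values that stayed on their side were short of the threshold throughout. The planned setting legacy=TRUE was not run apart, since the installed version uses it, and neither was a choice among several windows per gene, since each gene had 1. With 2 libraries or fewer per group, the depth and spread gave a median standard error of 0.257 for Nutlin3a without peptide and 0.440 for the difference among genes above the median abundance.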

Other observations

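The genes of the next paragraph and the windows of the one after it were chosen after their values were seen, as were the tests of treatment and of the inputs for small nucleolar RNA windows. The tests on miRNA windows were written first.

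Several windows beside or apart from p53 targets had positive values for Nutlin3a against DMSO without peptide, none past the threshold over all genes by edgeR's quasi-likelihood test. DINOL, a noncoding gene at CDKN1A whose window overlaps it, was at a log2 fold change of 1.31 ± 0.24 (SE, n = 2 per group), and ACTA2, which overlaps FAS, at 1.58 ± 0.34. MIR34AHG, the host gene of the tumour-suppressive microRNA miR-34a, was at 0.99 ± 0.26 without peptide and 1.34 with it. GRIN2C, a glutamate receptor subunit gene near the p53 target FDXR, was at 1.54 ± 0.31 and 1.49. LINC01136, which overlaps BTG2, was at 0.79, and SF3B6, near TP53I3, at 0.61 without and 1.55 with peptide. HELZ was at 0.84 without and 1.1 with peptide, and APOBEC3H, an antiviral deaminase gene, at 1.64 ± 0.40 without and 0.50 with it. The APOBEC3H window held 7.71 to 28.8 CPM in the ChIP libraries, below its input mean of 43.7 CPM. With DMSO it held 7.71 and 10.3 CPM without peptide and 17.9 CPM with it. With Nutlin3a the values were 27.5 and 28.8 CPM without peptide and 25.4 CPM with it.

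Mitochondrial ribosomal RNA windows differed between libraries. RNR1 had 431 CPM and RNR2 365 CPM in Nutlin3a replicate 1. The inputs held 3542 CPM at RNR1 and 1439 CPM at RNR2 on average. ROCK1P1, a pseudogene with near copies, had 145 CPM in DMSO replicate 1 and 349 CPM in Nutlin3a replicate 1, and 23.7, 49.8, 72.6 and 13.4 CPM in the replicate 2 libraries for DMSO, DMSO with peptide, Nutlin3a and Nutlin3a with peptide.

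Small nucleolar RNA windows, whose genes mostly lie in introns of other genes, had more counts in the replicate 1 than in the replicate 2 ChIP libraries. SNORD118 had 81.5 CPM in DMSO replicate 1 against 4.64 CPM in DMSO replicate 2. The median log2 ratio over 465 windows was 0.49 in the DMSO pair and 0.90 in the Nutlin3a pair, so Nutlin3a was argued against as the whole cause. In the inputs it was −0.060, inside the range of matched random lists (−0.17 to −0.05) but near its upper end. Counts pooled over the windows gave log2 ratios of 0.039 to 0.20 in the inputs, against 0.67 and 1.02 in the DMSO and Nutlin3a ChIP pairs. This argued against a difference of that size already in the sequenced chromatin. Polymerase over host gene bodies and small RNA reads were each predicted to raise a set of miRNA windows in both pairs. Windows of miRNAs inside another gene were at −0.069 in the DMSO pair and those of 29 abundant miRNAs at 0.0092, both inside their ranges. The Nutlin3a pair gave 0.46 and 0.47, both above their ranges. The predictions thus failed in the DMSO pair. The miRNA windows only stand in for the small nucleolar RNA windows, whose host genes and RNAs may differ, so both explanations stay open. MIR21, an abundant miRNA left out of the 29 because it had been seen, had 99.8 CPM in DMSO replicate 1 and 4.12 CPM in DMSO replicate 2, so small RNA reads stay open for its window.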
